A study of Mus musculus with 60 samples.

How the data were processed

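Per the labels, calf muscle of male mice was frozen and powdered, total RNA was extracted and labelled with biotin, and each of 60 animals was measured on 1 Affymetrix Mouse Gene 1.0 ST array without technical replicates. Per the submitters' processing notes the arrays were summarised with RMA in Affymetrix Expression Console, whose version is not given in the sources used here, and the deposited values are log2 expression values. They were used as the authors gave them, with no further scaling. The arrays of each age share their own level (means of 6.78 to 6.81 at 21 days, 7.19 to 7.27 at 3 months and 7.32 to 7.37 at 6 months), so expression was not compared directly between ages.

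The table holds 35556 probe sets. Of these 21789 carry 1 gene symbol, 1621 several and 12146 none that was used, and 21698 of the single-symbol ones were matched to a gene by Entrez identifier. Probe sets with several symbols or none were left out of the gene tests because no single gene could be named. For the 999 genes with more than 1 probe set the one with the highest mean over all arrays was kept, which left 19938 genes. No array was left out, no columns of values went unused, and no 2 arrays were identical.

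Gene tests used limma, with lmFit on a model of 12 group means over 60 arrays (48 residual degrees of freedom) and eBayes moderated t tests. P-values were adjusted by Benjamini and Hochberg within each comparison, and a gene passed with adjusted p under 0.05. The comparisons were each mutant with C57Bl/6 at each age, the mutants with each other, the non-additive part of the double mutant, and the difference of each mutant from C57Bl/6 at 3 and 6 months minus that at 21 days, 27 in all. Genes changed with age within a lineage had been planned and were not run, because the arrays of each age appear to have been normalised apart.

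Gene lists were written before the data were examined. They are 43 lists with 998 genes, of which 912 were measured, and cover the dystrophin complex, matrix, immune and other cell types, regeneration, fibre types, energy metabolism, stress and growth. Camera with a preset correlation of 0.01 tested the 41 lists with at least 5 measured genes, adjusted over all lists within a comparison. An estimated correlation and fry were run as alternatives. The comparisons, tests, thresholds, lists and settings, except those named below as chosen later, were chosen before the data were examined.

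Genes named in the text follow a fixed rule. For each comparison they are the 5 largest rises and 5 largest falls among genes that passed, leaving out predicted genes and, in comparisons of 2 groups, genes whose arrays overlapped between the groups. Dmd, Utrn and Dag1 were always named, 1 further gene planned with them is not reported here, and each list is illustrated by its members with the largest log2 fold changes among those that passed, in order of size, leaving out those already given in the paragraph.

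Overlaps between mutants were set beside the product of independent lists, 100 simulations of unchanged groups sharing their controls, and 20 splits of the controls. Each count was compared with 100 splits of the same arrays, or of residuals where a difference of differences was tested. Arrays whose marker means or named genes lay apart from the other 4 of their group were found with Dixon's test. Markers of lymph node, marrow, bone, cartilage, skin and mammary tissue and of sex were measured in every array.

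The gene test was run on data simulated from the means and variances of this series. These leave out correlation between genes, so the rates need not hold for the arrays. The test recovered 74.2% of changes of 0.5 log2 units, 94.0% of those of 1 and all of those of 2, with 5.5% false calls over 20 simulations, and at most 1 call where nothing changed. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.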

Results

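The series holds 60 arrays of calf muscle, 5 mice in each of 12 groups made of 4 lineages (C57Bl/6, Largemyd, Dmdmdx and the Dmdmdx/Largemyd double mutant) at 21 days, 3 months and 6 months. Values after a gene name are log2 fold changes±standard error from 5 arrays per group, and 19938 genes were tested in each comparison. Array means differ between ages, so every comparison below was made within an age or between differences taken within an age. The p-values describe replicate mice. In each comparison of 2 groups the genes named first are those with the largest rises and falls whose 5 and 5 arrays did not overlap, which chance gives to 0.79% of genes. All p-values are adjusted, and counts given as over the list alone are adjusted over the list alone.

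Dmd, which encodes dystrophin, was measured first because the Dmdmdx label predicts it. It fell in Dmdmdx at 21 days (-1.22±0.18), 3 months (-1.34±0.18) and 6 months (-0.93±0.18) and in the double mutant (-0.69±0.18, -1.09±0.18 and -1.09±0.18). It did not pass the test in Largemyd at any age (-0.12±0.18, -0.26±0.18 and -0.40±0.18). Utrn, the dystrophin homologue, did not pass the test in Dmdmdx at any age (-0.03±0.07, -0.01±0.07 and 0.17±0.07), and rose at 6 months in Largemyd (0.47±0.07) and the double mutant (0.29±0.07). Dag1, encoding dystroglycan, fell only in Largemyd at 6 months (-0.36±0.10). Without the arrays with high Xist, which leaves 1 control with marrow markers, the Utrn difference in Largemyd was 0.38 (adjusted p = 0.099) and that of Dag1 -0.02 (adjusted p = 0.96), and the fall of Dmd in Dmdmdx at 6 months was -0.60 (adjusted p = 0.25). Utrn in the double mutant was then 0.35 (adjusted p = 0.058). In Largemyd at 6 months Dmd passed without C57Bl/6 replicate 3 or Largemyd replicate 4 (adjusted p = 0.042 and 0.0080), with array medians subtracted (-0.47, adjusted p = 0.039) and with array weights (-0.52, adjusted p = 0.0020). With 19 arrays with markers of other tissue left out it passed at 3 and 6 months (-0.43 and -0.59, adjusted p = 0.032 and 0.0010). Utrn in Dmdmdx at 6 months passed with Xist and tissue markers as covariates (0.27, adjusted p = 0.0076). The plot of Dmd by lineage and age shows each array.

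**Figure D1:**
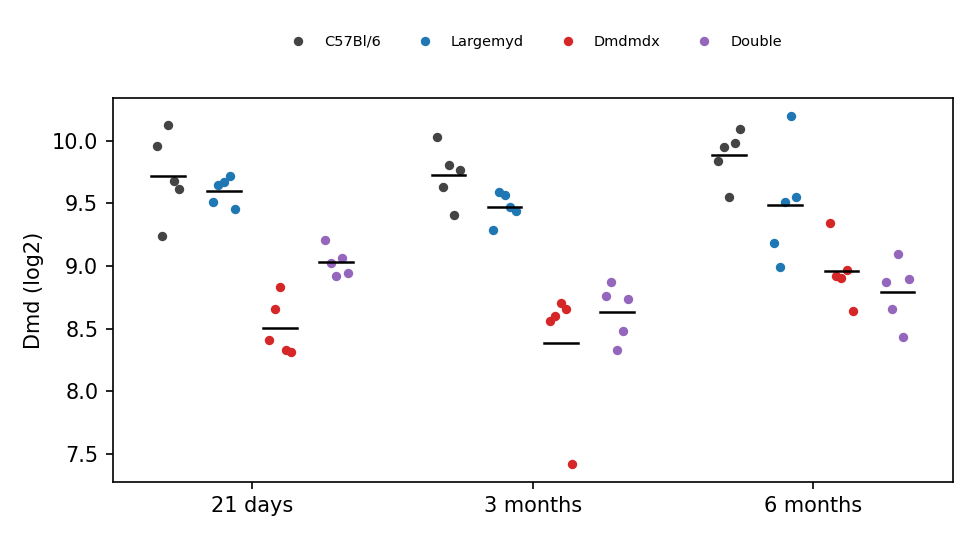
Dmd expression (log2, vertical axis) in each array by lineage and age (horizontal axis). Each point is 1 array and each bar is the mean of 5.

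All 60 arrays are labelled male, yet Xist, the transcript of the inactive X chromosome, was high and the Y-linked genes low in 11 of them. The lowest Xist value of the 11 was 10.58 and the highest of the other 49 was 5.85. The 11 are C57Bl/6 replicate 5 at 3 months and replicates 1, 2, 4 and 5 at 6 months, Largemyd replicates 2, 3 and 4 at 6 months, and Dmdmdx replicates 4 and 5 at 3 months and 4 at 6 months. Markers of other tissue lay more than 2 log2 units above the median of their age in 19 arrays, 4 of them among the 11. Lymph node markers were high in C57Bl/6 replicate 2, Largemyd 1 and Dmdmdx 1, 3 and 5 at 21 days, in Dmdmdx 5 at 3 months, and in Largemyd 2 and 4 at 6 months. Marrow markers were high in double mutant replicate 5 at 21 days, C57Bl/6 2, 3 and 4 and Dmdmdx 3 and 5 at 3 months, and C57Bl/6 1 and 3, Dmdmdx 5 and double mutant 4 at 6 months. Skin markers were high in double mutant replicates 2 and 3 at 21 days. Arrays so marked are called other-tissue arrays. All 60 were kept, and calls that ended without high-Xist or other-tissue arrays are given with each comparison. At 6 months leaving out the high-Xist arrays keeps 1 control, replicate 3, which has a marrow mean of 11.36, and the spread comes from the other groups. Calls ended against it do not test sex. The plot of Xist against the Y-linked genes shows all arrays.

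**Figure D2:**
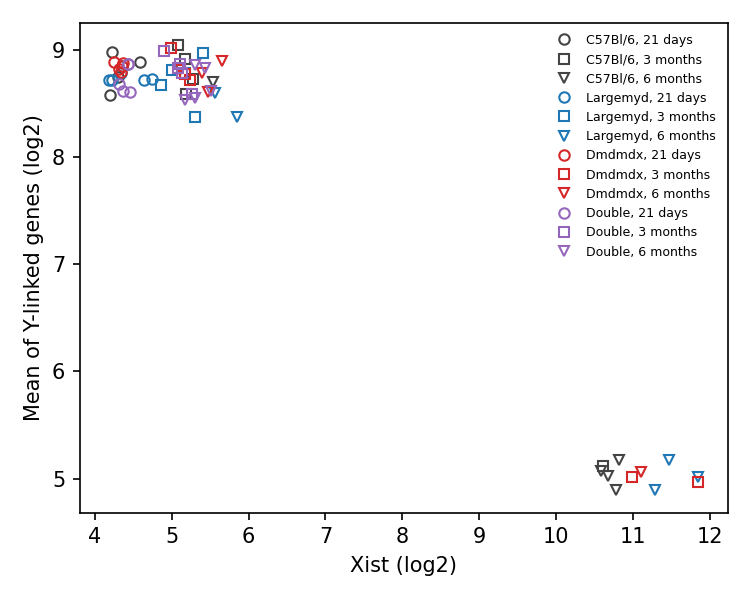
Xist (log2, horizontal axis) against the mean of the measured Y-linked genes (log2, vertical axis). Each point is 1 of 60 arrays, coloured by lineage, with the shape giving the age.

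In Largemyd at 21 days the largest rise was in H2-Ea (5.63±0.89), a class II gene that C57Bl/6 does not express because its promoter is deleted. It was followed by the proton pump subunit Atp6v0d2 (3.90±0.47), the chemokine Ccl3 (3.29±0.36), the macrophage glycoprotein Gpnmb (3.26±0.28) and embryonic myosin Myh3 (3.26±0.36). The largest falls were in Nxpe4 (-2.17±0.18), AA388235 (-2.05±0.22), the phospholipase Plcd4 (-1.96±0.35), Dhrs7c (-1.78±0.22) and myostatin (Mstn, -1.70±0.29). Of the macrophage markers 31 of 32 rose (32 over the list alone, camera p = 1.1e-35, or 0.030 with estimated correlation), such as Lgals3 (3.08±0.26) and Mpeg1 (3.04±0.37). Among proteases and their inhibitors 17 of 26 rose and 3 fell (17 and 3 over the list alone, camera p = 5.3e-11, or 0.0084 with estimated correlation), such as Mmp12 (2.80±0.35) and Timp1 (2.78±0.27). Of the matrix genes 20 of 39 rose (22 over the list alone, camera p = 2.5e-09, or 0.28 with estimated correlation), led by Tnc (1.17±0.34) and Postn (1.14±0.22). Genes of the regenerating sarcomere followed Myh3, and 12 of 23 rose and 1 fell (12 and 1 over the list alone, camera p = 1.5e-10, or 0.070 with estimated correlation), with Tnnt2 (3.12±0.30), Ankrd1 (2.81±0.25) and Myh8 (2.77±0.25) the largest. Of the oxidative phosphorylation genes 27 of 70 fell (36 over the list alone, camera p = 9.8e-10, or 0.49 with estimated correlation), such as Ndufb2 (-0.90±0.19) and Ndufc1 (-0.72±0.15). Of the endothelial markers 12 of 21 fell (13 over the list alone, camera p = 6.1e-07, or 0.28 with estimated correlation), such as Tek (-0.70±0.13) and Flt1 (-0.69±0.12). Limma's moderated test called 4589 genes, 1972 up and 2617 down, and 326 of them at 2-fold or more. With array medians subtracted 1542 rose and 3298 fell. The call of Tnc (without Largemyd 5, adjusted p = 0.074) was lost without 1 array.

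Dmdmdx at 21 days had its largest rises in genes of phagocytes, Atp6v0d2 (4.80±0.47), Ccl3 (4.28±0.36), Gpnmb (4.16±0.28), Mpeg1 (3.98±0.37) and the monocyte chemoattractant Ccl2 (3.67±0.38). Falls were largest in Lgi1 (-1.57±0.38), securin (Pttg1, -1.57±0.13), Tcea3 (-1.56±0.16), Mettl21c (-1.30±0.33) and Lrrc52 (-1.27±0.29). Among macrophage markers, 32 of 32 rose (32 over the list alone, camera p = 1.5e-55, or 0.0043 with estimated correlation), such as Lgals3 (3.63±0.26). Every measured cell cycle gene passed, and 31 of 31 rose (31 over the list alone, camera p = 1.3e-15, or 0.24 with estimated correlation), with Bub1 (2.19±0.46) and Ccna2 (2.07±0.52) the largest. Interferon-induced genes were raised, and 21 of 24 rose (22 over the list alone, camera p = 6.0e-16, or 0.18 with estimated correlation), led by Oasl2 (1.84±0.29), Ifit3 (1.82±0.35) and Irf7 (1.82±0.32). Of the MHC genes 12 of 13 rose (13 over the list alone, camera p = 8.7e-11, or 0.18 with estimated correlation), such as H2-Aa (1.91±0.29) and H2-Ab1 (1.89±0.34). Lymph node markers were high in 3 of the 5 Dmdmdx arrays and 1 of the 5 controls, and without them the interferon median went from 0.85 to 0.65. Of the oxidative phosphorylation genes 55 of 70 fell (64 over the list alone, camera p = 2.2e-15, or 0.30 with estimated correlation). Of the fatty acid oxidation genes 24 of 31 fell (24 over the list alone, camera p = 1.5e-09, or 0.23 with estimated correlation), such as Ppara (-1.07±0.19) and Ppargc1a (-0.90±0.33). Limma called 5018 genes, 2329 up and 2689 down, and 561 at 2-fold or more. With array weights the count was 8005, and with array medians subtracted 1831 rose and 4700 fell. The call of Ppargc1a (without any of 6 arrays, adjusted p = 0.051 to 0.12) was lost without 1 array, and without the other-tissue arrays (-0.80, adjusted p = 0.11).

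The double mutant at 21 days had its largest rises in the protease inhibitor Serpina3n (4.24±0.34), Atp6v0d2 (4.12±0.47), the complement receptor Vsig4 (4.09±0.32), Gpnmb (3.79±0.28) and lipocalin (Lcn2, 3.55±0.84). The largest falls were in Lgi1 (-2.99±0.38), the myelin protein Pmp2 (-2.92±0.22), the myosin kinase Mylk4 (-2.65±0.38), Plcd4 (-2.25±0.35) and Nnat (-2.12±0.49). For macrophage markers, 31 of 32 rose (31 over the list alone, camera p = 7.5e-25, or 0.13 with estimated correlation), such as Lgals3 (3.26±0.26) and Mpeg1 (2.86±0.37). The matrix genes split in direction, and 12 of 39 rose and 9 fell (12 and 9 over the list alone, camera p = 0.50, or 0.91 with estimated correlation), with Tnmd (-1.55±0.34), Thbs1 (1.52±0.21) and Col15a1 (-1.20±0.19) the largest. Of the oxidative phosphorylation genes 63 of 70 fell (67 over the list alone, camera p = 7.5e-25, or 0.23 with estimated correlation), such as Cox7a1 (-1.39±0.20) and Ndufc1 (-1.28±0.15). Of the endothelial markers 1 of 21 rose and 19 fell (1 and 19 over the list alone, camera p = 6.3e-11, or 0.15 with estimated correlation), such as Kdr (-1.05±0.16) and Ptprb (-0.96±0.12). Of the atrophy genes 7 of 21 rose and 1 fell (10 and 1 over the list alone, camera p = 0.0014, or 0.49 with estimated correlation), with Mt1 (2.50±0.26), Mt2 (2.13±0.24) and Fbxo32 (1.32±0.42) the largest. Marrow markers were high in replicate 5 and skin markers in replicates 2 and 3. Limma called 6759 genes, 3076 up and 3683 down, and 540 at 2-fold or more. The call of Fbxo32 (without double mutant 1 or 5, adjusted p = 0.099 to 0.12) was lost without 1 array and with array weights (0.55, adjusted p = 0.19). Without double mutant 1 or with array weights that of the atrophy list ended (adjusted p = 0.055 and 0.17).

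In Largemyd at 3 months the largest rises were in H2-Ea (5.94±0.89), macrophage elastase (Mmp12, 4.09±0.35), Gpnmb (3.40±0.28), the histidine-degrading enzyme Hal (3.36±0.56) and the kallikrein Klk1b22 (3.05±0.46). Falls were largest in genes of neutrophils and bone, Ngp (-4.28±1.27), Ibsp (-3.29±0.91), S100a8 (-3.26±1.01), S100a9 (-2.92±0.90) and Ltf (-2.74±0.88). Marrow markers, which include Ngp, S100a8, S100a9 and Ltf, were high in 3 of the 5 C57Bl/6 arrays. Without the other-tissue arrays the 5 falls were -3.28, -2.98, -2.35, -2.22 and -1.91 and all passed, yet marrow was not removed, as the 2 controls left had marrow means of 8.16 and 8.09 against 6.31 to 7.19 in Largemyd. Without C57Bl/6 replicate 3 alone S100a8 (-2.60, adjusted p = 0.079), S100a9 (-2.41, adjusted p = 0.068) and Ltf (-2.18, adjusted p = 0.092) did not pass. With Xist and tissue markers as covariates Ibsp did not pass (-0.50, adjusted p = 0.23), and for the other 4, part of the marrow covariate, that fit is no test. Of the macrophage markers 29 of 32 rose (31 over the list alone, camera p = 7.2e-33, or 0.022 with estimated correlation), such as Atp6v0d2 (2.90±0.47) and Lgals3 (2.62±0.26). Among matrix genes, 30 of 39 rose (32 over the list alone, camera p = 2.6e-27, or 0.016 with estimated correlation), such as Postn (1.70±0.22) and Mfap4 (1.70±0.27). Among proteases and their inhibitors 18 of 26 rose and 2 fell (18 and 6 over the list alone, camera p = 1.4e-15, or 0.00072 with estimated correlation), such as Ctss (2.87±0.29) and Timp1 (2.82±0.27). Imprinted growth genes, most active before birth, were raised, and 10 of 14 rose (11 over the list alone, camera p = 2.7e-09, or 0.049 with estimated correlation), led by Igf2 (2.21±0.21), Mest (2.02±0.35) and Peg3 (1.61±0.17). Of the neutrophil markers 6 of 14 fell (9 over the list alone, camera p = 0.00021, or 0.48 with estimated correlation), and the median went from -2.19 to -1.07 without the other-tissue arrays and 0.28 with the covariates, which share genes with it. Limma called 3773 genes, 2104 up and 1669 down, and 349 at 2-fold or more. With array weights the count was 6500, and with array medians subtracted 1632 rose and 2454 fell.

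Dmdmdx at 3 months had its largest rises in Ccl7 (3.17±0.39), Gpnmb (3.10±0.28), the C3a receptor C3ar1 (3.08±0.26), Ms4a6d (3.05±0.28) and Mmp12 (3.04±0.35). The largest falls were in the muscle-secreted peptide osteocrin (Ostn, -2.22±0.26), Pttg1 (-1.70±0.13), neuronal nitric oxide synthase (Nos1, -1.70±0.21), Lrrc52 (-1.69±0.29) and Mstn (-1.68±0.29). Among macrophage markers, 31 of 32 rose (31 over the list alone, camera p = 1.1e-38, or 0.018 with estimated correlation), such as Ms4a7 (2.94±0.24) and Atp6v0d2 (2.76±0.47). For matrix genes, 27 of 39 rose (32 over the list alone, camera p = 1.2e-17, or 0.066 with estimated correlation), such as Postn (1.95±0.22) and Lox (1.49±0.15). Of the complement genes 12 of 18 rose and 1 fell (12 and 2 over the list alone, camera p = 9.7e-10, or 0.018 with estimated correlation), such as C1qb (1.95±0.17) and C1qc (1.75±0.19). Of the interferon-induced genes 18 of 24 rose (18 over the list alone, camera p = 5.3e-09, or 0.24 with estimated correlation), such as Oasl2 (1.40±0.29) and Irf7 (1.33±0.32). Energy genes went down. For oxidative phosphorylation 53 of 70 fell (61 over the list alone, camera p = 4.8e-15, or 0.28 with estimated correlation). For fatty acid oxidation 29 of 31 fell (29 over the list alone, camera p = 8.7e-15, or 0.095 with estimated correlation), such as Ucp3 (-1.39±0.25) and Ppara (-1.07±0.19). Clock genes were lower, and 12 of 16 fell (12 over the list alone, camera p = 0.00012, or 0.14 with estimated correlation), such as Ciart (-1.18±0.32), Hlf (-1.16±0.17) and Bhlhe41 (-1.02±0.21). Replicates 4 and 5 had high Xist, and replicate 5 carried lymph node and marrow markers. Limma called 5606 genes, 2457 up and 3149 down, and 531 at 2-fold or more. The count was 3130 without the high-Xist arrays, 3625 without those with other-tissue markers and 3184 with these 10 arrays alone. Calls lost were Ciart (-0.96, adjusted p = 0.12) and Irf7 (1.13, adjusted p = 0.055) without the high-Xist arrays and Bhlhe41 (-0.44, adjusted p = 0.18) and Ciart (-0.65, adjusted p = 0.38) without those with other-tissue markers. Without the latter the list medians went from -0.63 to -0.39 (clock), -0.41 to -0.24 (oxidative phosphorylation) and 0.55 to 1.07 (complement).

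The double mutant at 3 months had its largest rises in Mmp12 (4.50±0.35), the chemokine Ccl8 (3.54±0.38), Gpnmb (3.52±0.28), Myh3 (3.44±0.36) and Ms4a7 (3.37±0.24). Falls were largest in Ngp (-4.82±1.27), Ibsp (-3.23±0.91), S100a8 (-3.15±1.01), Ostn (-3.13±0.26) and Ltf (-2.96±0.88). Marrow markers were high in 3 of the 5 controls, and without the other-tissue arrays Ngp, S100a8 and Ltf were -3.82, -2.23 and -2.14. With the covariates Ibsp did not pass (-0.33, adjusted p = 0.38). Without C57Bl/6 replicate 3 S100a8 was -2.49 (adjusted p = 0.064). Of the matrix genes 36 of 39 rose (36 over the list alone, camera p = 1.2e-29, or 0.010 with estimated correlation), such as Postn (2.45±0.22), Col8a1 (2.0±0.20) and Mfap4 (1.98±0.27). Of the markers of fibro-adipogenic progenitors 15 of 21 rose (16 over the list alone, camera p = 3.9e-08, or 0.055 with estimated correlation), such as Col6a1 (1.18±0.13) and Mfap5 (1.10±0.15). For macrophage markers, 31 of 32 rose (31 over the list alone, camera p = 1.2e-35, or 0.015 with estimated correlation), such as Ms4a6d (3.33±0.28) and Atp6v0d2 (3.29±0.47). Among complement genes, 13 of 18 rose and 1 fell (13 and 1 over the list alone, camera p = 2.9e-11, or 0.010 with estimated correlation). Of the imprinted growth genes 13 of 14 rose (13 over the list alone, camera p = 9.4e-11, or 0.027 with estimated correlation), led by Mest (2.52±0.35), Igf2 (2.33±0.21) and Peg3 (1.88±0.17). Of the genes of the tricarboxylic acid cycle and linked amino acid metabolism 22 of 23 fell (23 over the list alone, camera p = 5.1e-10, or 0.17 with estimated correlation), such as Bckdhb (-1.03±0.18) and Got1 (-0.96±0.15). Limma called 5997 genes, 2913 up and 3084 down, and 674 at 2-fold or more. Array weights gave 9236, and subtracting array medians 2419 up and 4139 down.

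In Largemyd at 6 months the largest rises were in Ccl8 (3.78±0.38), Hal (2.77±0.56), C3ar1 (2.69±0.26), Serpina3n (2.68±0.34) and cathepsin S (Ctss, 2.56±0.29). The largest falls were in Ostn (-3.16±0.26), Mstn (-2.63±0.29), Mettl11b (-2.43±0.27), Chac1 (-2.33±0.37) and Plcd4 (-2.31±0.35). Nearly all matrix genes were raised, and 38 of 39 rose (38 over the list alone, camera p = 1.3e-26, or 0.017 with estimated correlation), such as Sfrp1 (2.31±0.23), Postn (2.01±0.22) and Mfap4 (1.82±0.27). Of the macrophage markers 29 of 32 rose (31 over the list alone, camera p = 2.0e-21, or 0.085 with estimated correlation), such as Ms4a7 (2.47±0.24) and Ms4a6d (2.34±0.28). Of the MHC genes 13 of 13 rose (13 over the list alone, camera p = 2.7e-07, or 0.26 with estimated correlation), such as H2-Aa (1.83±0.29) and Cd74 (1.79±0.30). Lymph node markers were high in replicates 2 and 4 and raised in 1 and 5 (8.53 and 8.34). Without the other-tissue arrays the MHC median went from 0.75 to 0.60. Energy genes were lower. For oxidative phosphorylation 56 of 70 fell (62 over the list alone, camera p = 1.5e-13, or 0.36 with estimated correlation). For glycolysis 23 of 25 fell (23 over the list alone, camera p = 2.6e-11, or 0.20 with estimated correlation), such as Fbp2 (-1.67±0.22) and Phkg1 (-1.58±0.22). Of the fast fibre genes 13 of 18 fell (14 over the list alone, camera p = 1.2e-08, or 0.22 with estimated correlation), such as Mylk2 (-1.64±0.26) and Ampd1 (-1.35±0.17). Of the fat cell markers 8 of 16 rose (9 over the list alone, camera p = 0.0032, or 0.44 with estimated correlation), such as Pck1 (1.54±0.41) and Cidec (1.08±0.42). Limma called 6483 genes, 3076 up and 3407 down, and 615 at 2-fold or more, and with array medians subtracted 2320 rose and 4516 fell. Xist was high in 4 of the 5 C57Bl/6 and 3 of the 5 Largemyd arrays, and without them 1 control, with marrow markers, was left. Calls of Cd74, Chac1, Cidec, Ctss, Fbp2, H2-Aa, H2-Ea, Hal, Mfap4, Mylk2, Pck1, Phkg1, Plcd4 and Postn then ended. So did that of the fat cell list. With the covariates, which keep all arrays, 5633 of the 6483 calls held. The call of Cidec was lost without any 1 of 7 arrays (adjusted p = 0.052 to 0.11) and without the other-tissue arrays (1.04, adjusted p = 0.15). The mammary mean of replicate 4 was high (8.31).

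Dmdmdx at 6 months had its largest rises in C3ar1 (3.35±0.26), the aldo-keto reductase Akr1e1 (3.24±0.43), Ms4a7 (3.10±0.24), Gpnmb (2.95±0.28) and Mmp12 (2.93±0.35). Falls were largest in Ostn (-3.68±0.26), Lgi1 (-2.12±0.38), Pttg1 (-2.04±0.13), Ces1d (-2.0±0.44) and Pla2g5 (-1.84±0.17). Among matrix genes, 28 of 39 rose (31 over the list alone, camera p = 1.2e-30, or 0.0065 with estimated correlation), such as Postn (1.96±0.22) and Col3a1 (1.41±0.17). Among macrophage markers, 30 of 32 rose (31 over the list alone, camera p = 2.0e-52, or 0.0022 with estimated correlation), such as Ms4a6d (2.82±0.28) and Mpeg1 (2.71±0.37). Of the complement genes 13 of 18 rose (14 over the list alone, camera p = 7.7e-17, or 0.00062 with estimated correlation), such as C7 (2.25±0.69) and C1qb (1.98±0.17). Of the genes of cholesterol and fatty acid synthesis 12 of 21 fell (12 over the list alone, camera p = 6.7e-05, or 0.15 with estimated correlation), such as Fasn (-1.74±0.31), Elovl6 (-1.56±0.29) and Scd1 (-1.05±0.27). Of the fatty acid oxidation genes 17 of 31 fell (20 over the list alone, camera p = 1.4e-09, or 0.15 with estimated correlation), such as Ppara (-0.78±0.19) and Ucp3 (-0.77±0.25). Limma called 2763 genes, 1419 up and 1344 down, and 307 at 2-fold or more. Xist was high in 4 control arrays and Dmdmdx replicate 4, so sex and lineage are largely confounded here. Without these arrays 1 control, with marrow markers, was left, and the calls of C7, Ces1d, Elovl6, Fasn, Lgi1, Mpeg1, Ppara, Scd1 and Ucp3 ended. Those of C7 (without any of 5 arrays, adjusted p = 0.052 to 0.067), Ucp3 (without any of 5 arrays, adjusted p = 0.058 to 0.16) and Scd1 (without Dmdmdx 1, adjusted p = 0.052) were lost without 1 array. Without those with other-tissue markers that of Ucp3 (-0.71, adjusted p = 0.070) ended. With array weights the count was 6214 and with the covariates 4552.

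The double mutant at 6 months had its largest rises in Ccl8 (4.11±0.38), Ms4a6d (3.58±0.28), Mmp12 (3.53±0.35), complement C7 (3.44±0.69) and the protease inhibitor Timp1 (3.35±0.27). The largest falls were in Xist (-4.33±1.11), Ostn (-3.90±0.26), Mettl11b (-2.34±0.27), Asb4 (-2.29±0.13) and Mstn (-2.26±0.29). As 4 of the 5 controls and no double mutant had high Xist, sex and lineage are largely confounded here. The fall of Xist is a difference of arrays, and it was -0.19 without those with high Xist. Against the 1 control then left, which has marrow markers, the calls of Atp6v0d2, Bckdhb, C7 and Id2 ended. For matrix genes, 37 of 39 rose (37 over the list alone, camera p = 2.8e-34, or 0.0044 with estimated correlation), such as Sfrp1 (2.53±0.23), Postn (2.29±0.22) and Col8a1 (1.89±0.20). Of the TGF-beta genes 12 of 27 rose and 1 fell (15 and 3 over the list alone, camera p = 9.6e-05, or 0.027 with estimated correlation), such as Tgfbi (1.27±0.11) and Id2 (1.26±0.18). For macrophage markers, 32 of 32 rose (32 over the list alone, camera p = 3.3e-36, or 0.011 with estimated correlation), such as Ms4a7 (3.25±0.24) and Atp6v0d2 (3.21±0.47). Among complement genes, 14 of 18 rose (14 over the list alone, camera p = 3.3e-17, or 0.00052 with estimated correlation). Among proteases and their inhibitors 19 of 26 rose (19 over the list alone, camera p = 7.6e-18, or 0.00022 with estimated correlation), such as Ctss (3.09±0.29) and Mmp3 (2.76±0.20). Of the genes of the tricarboxylic acid cycle and linked amino acid metabolism 20 of 23 fell (20 over the list alone, camera p = 5.8e-07, or 0.24 with estimated correlation), such as Bckdhb (-0.89±0.18) and Suclg2 (-0.73±0.10). Limma called 5945 genes, 2862 up and 3083 down, and 661 at 2-fold or more. With array medians subtracted 2456 rose and 4397 fell.

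**Figure D3:**
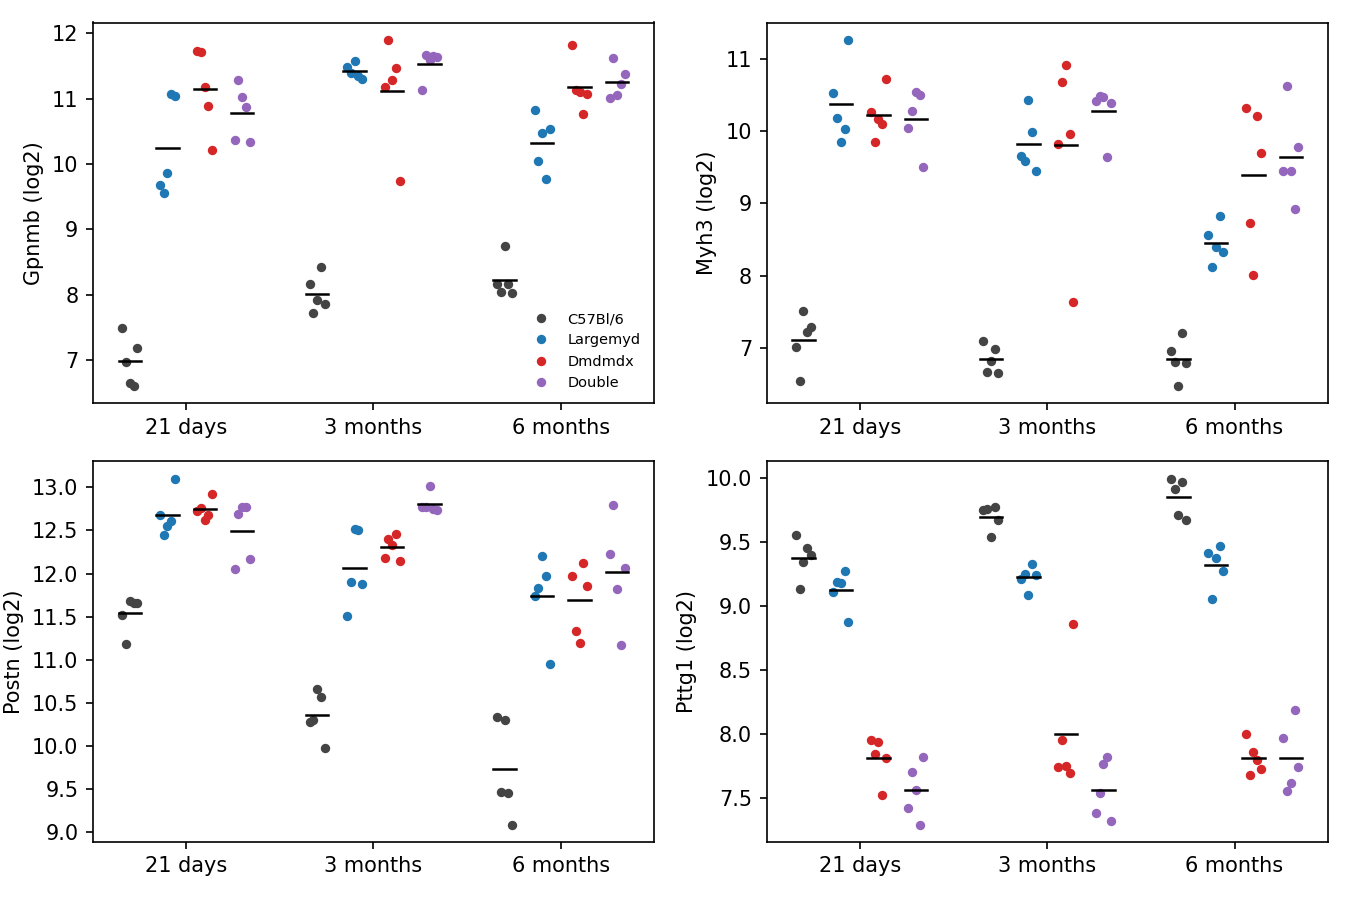
Gpnmb, Myh3, Postn and Pttg1 expression (log2, vertical axes) by lineage and age (horizontal axes). Each point is 1 array and each bar is the mean of 5.

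At 21 days Largemyd exceeded Dmdmdx most in H2-Ea (5.74±0.89), Hal (2.38±0.56), the mast cell tryptase Tpsab1 (1.87±0.15), Mir136 (1.54±0.27) and Rps3a1 (1.32±0.16). Lowest against it were Ifi213 (-2.41±0.41), Ms4a4c (-2.26±0.48), Ifi209 (-2.09±0.58), Cyp4f18 (-2.09±0.36) and Ccr2 (-2.0±0.33). Of the interferon-induced genes 17 of 24 fell (20 over the list alone, camera p = 1.4e-15, or 0.45 with estimated correlation), such as Oasl2 (-1.45±0.29) and Irf7 (-1.39±0.32). Lymph node markers were high in 3 of the 5 Dmdmdx arrays, and the list median went from -0.68 to -0.29 without the other-tissue arrays. The double mutant exceeded Dmdmdx most in Inmt (2.20±0.48), Slc10a6 (1.88±0.34), Vsig4 (1.86±0.32), Lvrn (1.75±0.29) and the glucocorticoid-induced Fkbp5 (1.73±0.34). Its lowest values were in Ifi213 (-2.52±0.41), Retnla (-2.52±0.39), Ms4a4c (-2.37±0.48), Ifi209 (-2.33±0.58) and Mylk4 (-2.28±0.38). Of the MHC genes 12 of 13 fell (12 over the list alone, camera p = 7.1e-10, or 0.61 with estimated correlation). Of the matrix genes 1 of 39 rose and 16 fell (1 and 18 over the list alone, camera p = 5.3e-05, or 0.70 with estimated correlation), such as Tnmd (-1.26±0.34) and Col15a1 (-1.09±0.19). Of the atrophy genes 14 of 21 rose and 1 fell (17 and 1 over the list alone, camera p = 1.2e-05, or 0.70 with estimated correlation), such as Mt1 (1.57±0.26), Fbxo32 (1.55±0.42) and Trim63 (1.38±0.38). The double mutant exceeded Largemyd most in Prg4 (1.38±0.24), Snord53 (1.36±0.28), Lrmda (1.34±0.14), Nxpe4 (1.33±0.18) and Olfr1372-ps1 (1.25±0.14). Lowest were Mss51 (-1.72±0.33), Pmp2 (-1.66±0.22), Pttg1 (-1.57±0.13), Lgi1 (-1.55±0.38) and Kera (-1.49±0.34). Limma called 1782, 5475 and 1104 genes (773, 2765 and 347 up). Leaving out 1 array moved these counts. The first was 913, 819, 957 and 1155 without Largemyd replicates 1 and 2 and Dmdmdx 1 and 3. The second was 3582 without double mutant 1. For the last it was 1923, 548 and 636 without Largemyd 2 and 3 and double mutant 1. Calls lost that way were Ifi209 (without any of 4 arrays, adjusted p = 0.058 to 0.072). For the double mutant they were Fbxo32 (without double mutant 1, adjusted p = 0.062), Tnmd (without double mutant 1, adjusted p = 0.051) and Trim63 (without double mutant 1, adjusted p = 0.067) against Dmdmdx and Lgi1 (without double mutant 1, adjusted p = 0.060) against Largemyd. Without the other-tissue arrays the first 2 counts were 374 and 2060. The calls of Hal (2.54, adjusted p = 0.12), Ifi209 (-1.13, adjusted p = 0.17), Irf7 (-0.73, adjusted p = 0.29), Ms4a4c (-1.32, adjusted p = 0.072) and Oasl2 (-0.93, adjusted p = 0.19) against Dmdmdx and Snord53 (1.08, adjusted p = 0.12) against Largemyd ended. Array weights ended the calls of Tnmd (-0.55, adjusted p = 0.098) and Trim63 (0.63, adjusted p = 0.053) against Dmdmdx and Kera (-0.94, adjusted p = 0.073) against Largemyd. Without dim genes (lower 50%) the second count was 3214. The first and last were 734 and 366 with arrays of that age alone and 723 and 45 with 2 groups alone, and the last was 1754 with the covariates. With array medians subtracted the splits were 1021 up and 832 down, 4074 and 1997, and 356 and 497.

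At 3 months Largemyd exceeded Dmdmdx most in H2-Ea (5.91±0.89), Klk1b22 (3.42±0.46), Hal (3.18±0.56), Pttg1 (1.23±0.13) and the uncoupling protein Ucp3 (1.14±0.25). It was lowest in Chil3 (-3.12±0.83), Ly6a2 (-3.05±0.90), Cyp4f18 (-2.15±0.36), Ms4a4c (-1.98±0.48) and Ifi209 (-1.90±0.58). The double mutant exceeded Dmdmdx most in Snord53 (1.84±0.28), Vsig4 (1.52±0.32), Mmp12 (1.46±0.35), Pianp (1.29±0.15) and the cartilage protein Cilp (1.28±0.21). Its lowest values were in Alas2 (-1.91±0.53), Akr1e1 (-1.71±0.43), Rsad2 (-1.44±0.38), Cyp4f18 (-1.32±0.36) and Klra2 (-1.21±0.29). Among matrix genes, 14 of 39 rose (22 over the list alone, camera p = 2.3e-20, or 0.044 with estimated correlation), such as Mfap4 (1.15±0.27), Col6a3 (1.11±0.18) and Thbs4 (0.92±0.15). Of the basement membrane genes 10 of 27 rose (14 over the list alone, camera p = 1.5e-13, or 0.042 with estimated correlation). Of the markers of fibro-adipogenic progenitors 8 of 21 rose (12 over the list alone, camera p = 1.3e-11, or 0.042 with estimated correlation). The double mutant exceeded Largemyd most in Snord53 (1.96±0.28), Snord73b (1.67±0.34), Nxpe4 (1.56±0.18), Lrmda (1.49±0.14) and Sh2d1b1 (1.36±0.25). Lowest were Klk1b22 (-3.26±0.46), Akr1e1 (-1.69±0.43), Pttg1 (-1.66±0.13), Ublcp1 (-1.28±0.19) and Ppp1r3c (-1.23±0.28). Limma called 845, 402 and 227 genes (640, 337 and 73 up). Leaving out 1 array moved all 3 counts. The first was 437, 554, 1394 and 227 without Largemyd replicates 1 and 3 and Dmdmdx 1 and 5. The second was 206, 264, 249 and 254 without Dmdmdx 5 and double mutant 2, 3 and 4. For the last it was 151, 136, 119 and 103 without Largemyd 2 and 5 and double mutant 3 and 4. Calls of Largemyd against Dmdmdx lost that way were Ifi209 (without any of 8 arrays, adjusted p = 0.051 to 0.27), Ly6a2 (without any of 6 arrays, adjusted p = 0.064 to 0.29), Chil3 (without Dmdmdx 5, adjusted p = 0.18) and Ms4a4c (without Dmdmdx 5, adjusted p = 0.073). In the double mutant against Dmdmdx they were Cyp4f18 (without any of 7 arrays, adjusted p = 0.055 to 0.18), Alas2 (without any of 7 arrays, adjusted p = 0.053 to 0.29), Klra2 (without Dmdmdx 5, adjusted p = 0.12), Mfap4 (without Dmdmdx 5, adjusted p = 0.087), Mmp12 (without Dmdmdx 5, adjusted p = 0.088), Rsad2 (without any of 5 arrays, adjusted p = 0.058 to 0.23) and Akr1e1 (without double mutant 1 or 5, adjusted p = 0.11 to 0.11). Against Largemyd it was Akr1e1 (without any of 6 arrays, adjusted p = 0.063 to 0.15). Without the high-Xist arrays the counts were 127, 150 and 359, and without those with other-tissue markers 327, 254 and 790. With the high-Xist arrays left out the calls of Chil3 (-2.59, adjusted p = 0.23), Ifi209 (-1.45, adjusted p = 0.50), Ly6a2 (-2.79, adjusted p = 0.23), Ms4a4c (-1.86, adjusted p = 0.15) and Ucp3 (0.99, adjusted p = 0.064) ended for Largemyd. Those of Alas2 (-1.35, adjusted p = 0.43), Cyp4f18 (-1.18, adjusted p = 0.28), Klra2 (-0.89, adjusted p = 0.27), Mfap4 (0.94, adjusted p = 0.18), Mmp12 (1.29, adjusted p = 0.16) and Rsad2 (-1.07, adjusted p = 0.33) ended for the double mutant. Leaving out the other-tissue arrays ended those of Ucp3 (0.87, adjusted p = 0.092) for Largemyd and Akr1e1 (-1.85, adjusted p = 0.052), Alas2 (-0.98, adjusted p = 0.10), Mfap4 (0.86, adjusted p = 0.053), Mmp12 (1.09, adjusted p = 0.14) and Rsad2 (-0.93, adjusted p = 0.080) for the double mutant. With array weights the counts were 1862, 1382 and 2700, and with 2 groups alone 88, 143 and 1327. The first was 471 with arrays of that age alone, and the first and last were 180 and 528 with the covariates. Largemyd against Dmdmdx split as 398 up and 251 down with array medians subtracted and as 666 and 356 with quantile normalization.

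At 6 months Largemyd exceeded Dmdmdx most in H2-Ea (4.76±0.89), the immunoglobulin gene Igkv10-96 (3.39±0.93), Hal (2.74±0.56), fatty acid synthase (Fasn, 2.64±0.31) and Cd3g (2.29±0.76). It was lowest in Mir1a-2 (-1.91±0.46), Plcd4 (-1.81±0.35), Chac1 (-1.78±0.37), Nt5c1a (-1.47±0.20) and Mir133a-1 (-1.36±0.34). Of the fat cell markers 12 of 16 rose (14 over the list alone, camera p = 7.4e-11, or 0.16 with estimated correlation), such as Retn (2.11±0.42) and Pck1 (2.03±0.41). Of the genes of cholesterol and fatty acid synthesis 11 of 21 rose and 1 fell (12 and 1 over the list alone, camera p = 2.0e-07, or 0.16 with estimated correlation). Lymph node means were 8.34 to 10.49 in Largemyd, except replicate 3 (7.01), and 6.58 to 6.99 in Dmdmdx. The part of lymph node in Igkv10-96 and Cd3g stays open. The double mutant exceeded Dmdmdx most in Vsig4 (2.67±0.32), Ccl8 (1.38±0.38), Rrad (1.35±0.29), Ocel1 (1.30±0.08) and Lyve1 (1.28±0.24). Its lowest values were in Chac1 (-1.60±0.37), Mc5r (-1.59±0.20), Pfkfb3 (-1.44±0.27), Plcd4 (-1.38±0.35) and Klhl33 (-1.29±0.18). For matrix genes, 12 of 39 rose (25 over the list alone, camera p = 3.4e-19, or 0.045 with estimated correlation), such as Sfrp1 (1.19±0.23) and Comp (1.13±0.23). Of the complement genes 8 of 18 rose (11 over the list alone, camera p = 2.4e-09, or 0.041 with estimated correlation). The double mutant exceeded Largemyd most in Prg4 (1.70±0.24), Olfr1372-ps1 (1.5±0.14), Mmp12 (1.30±0.35), Ms4a4a (1.24±0.26) and Lrmda (1.10±0.14). Lowest were Snord53 (-1.57±0.28), Pttg1 (-1.51±0.13), Pnpla3 (-0.95±0.19), Krt19 (-0.85±0.21) and Ublcp1 (-0.78±0.19). Limma called 2843, 913 and 268 genes (1209, 504 and 106 up). Leaving out 1 array moved these counts. The first was 1677 without Largemyd replicate 2. The second was 592 and 590 without Dmdmdx 4 and double mutant 5. For the last it was 71, 139, 109 and 140 without Largemyd 2 and double mutant 1, 2 and 5. Calls lost that way were Cd3g (without any of 6 arrays, adjusted p = 0.055 to 0.13) and Igkv10-96 (without Largemyd 2, adjusted p = 0.068) between the single mutants. For the double mutant they were Ccl8 (without any of 4 arrays, adjusted p = 0.051 to 0.084) and Plcd4 (without double mutant 4, adjusted p = 0.051) against Dmdmdx. Against Largemyd they were Krt19 (without any of 5 arrays, adjusted p = 0.056 to 0.18), Mmp12 (without any of 5 arrays, adjusted p = 0.083 to 0.18) and Ublcp1 (without Largemyd 2 or double mutant 2 or 3, adjusted p = 0.063 to 0.071). Without the high-Xist arrays the first and last counts were 490 and 16. The calls of Cd3g (2.29, adjusted p = 0.21), Chac1 (-1.74, adjusted p = 0.076), H2-Ea (2.99, adjusted p = 0.21), Igkv10-96 (2.88, adjusted p = 0.20), Pck1 (1.84, adjusted p = 0.090), Plcd4 (-1.38, adjusted p = 0.12) and Retn (1.94, adjusted p = 0.075) against Dmdmdx then ended. So did that of Ccl8 (1.28, adjusted p = 0.078) for the double mutant, and against Largemyd those of Krt19 (-0.29, adjusted p = 0.45), Mmp12 (0.85, adjusted p = 0.47), Ms4a4a (1.43, adjusted p = 0.11), Pnpla3 (-0.70, adjusted p = 0.32), Snord53 (-1.64, adjusted p = 0.11) and Ublcp1 (-0.74, adjusted p = 0.37). Without the other-tissue arrays the last count was 161 and Krt19 (-0.34, adjusted p = 0.20), Mmp12 (0.81, adjusted p = 0.42), Ms4a4a (1.16, adjusted p = 0.065), Pnpla3 (-0.72, adjusted p = 0.15), Snord53 (-1.46, adjusted p = 0.057) and Ublcp1 (-0.81, adjusted p = 0.11) did not pass. The last 2 were 3019 and 746 with array weights and 1526 and 70 with the covariates, and the last was 8 with 2 groups alone. With array medians subtracted the splits were 798 up and 2180 down, 399 and 498, and 124 and 100, and with quantile normalization the second was 558 and 697.

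Additivity of log2 values and 1 strain background were assumed here, not tested, so a departure need not mean that the mutations interact. The double mutant would then differ from C57Bl/6 by the sum of both single-mutant differences. At 21 days it fell short of that sum most in Atp6v0d2 (-4.58±0.67), Ccl3 (-4.27±0.51), Mpeg1 (-4.16±0.53), Akr1e1 (-4.12±0.60) and Ccl8 (-3.68±0.53). It exceeded the sum most in Inmt (2.35±0.67), Cish (2.04±0.51), Dhrs7c (1.90±0.32), Depp1 (1.84±0.55) and Hamp (1.81±0.48). At 3 months it fell short most in Akr1e1 (-4.69±0.60), Gpnmb (-2.98±0.40), Klk1b22 (-2.89±0.65), Mmp12 (-2.62±0.50) and C3ar1 (-2.57±0.37). Above the sum were Rny1 (1.87±0.52), Nxpe4 (1.84±0.26), Ciart (1.81±0.46), Snord53 (1.69±0.40) and Hlf (1.45±0.25). At 6 months it fell short most in C3ar1 (-2.75±0.37), Ccl8 (-2.41±0.53), Ctss (-2.38±0.41), Ms4a7 (-2.33±0.33) and Cd180 (-2.31±0.58). Above the sum were Ostn (2.94±0.37), Lrrc52 (2.07±0.41), Otub2 (1.93±0.22), Alpk2 (1.81±0.29) and Ppp1r3c (1.79±0.39). Of the macrophage markers 31 of 32 fell (31 over the list alone, camera p = 9.1e-45, or 0.0093 with estimated correlation) at 21 days. At 3 months 19 of 32 fell (28 over the list alone, camera p = 6.1e-34, or 0.019 with estimated correlation), and at 6 months 16 of 32 fell (25 over the list alone, camera p = 9.2e-25, or 0.073 with estimated correlation). Of the proteases and inhibitors 3 of 26 rose and 15 fell (3 and 16 over the list alone, camera p = 3.5e-10, or 0.0093 with estimated correlation) at 21 days, such as Ctss (-3.53±0.41) and Timp1 (-2.96±0.39). Clock genes exceeded the sum at 3 months, where 6 of 16 rose (11 over the list alone, camera p = 1.5e-09, or 0.016 with estimated correlation). Limma called 3030, 635 and 1001 genes (1285, 263 and 592 above the sum). At 3 months the count was 422 without C57Bl/6 replicate 2, and at 6 months 662, 644 and 627 without C57Bl/6 2, Largemyd 2 and double mutant 3. Calls lost without 1 array were Depp1 (without Largemyd 4 or 5 or double mutant 1, adjusted p = 0.052 to 0.069) and Inmt (without Largemyd 5, adjusted p = 0.052) at 21 days. At 3 months it was Rny1 (without any of 6 arrays, adjusted p = 0.050 to 0.082). With the high-Xist arrays left out the count was 299 at 3 months. At 6 months 1 control was left and the calls of Ccl8, Cd180, Ctss, Lrrc52, Ms4a7, Ostn and Ppp1r3c ended. At 3 months those of Ciart (1.59, adjusted p = 0.15), Rny1 (1.80, adjusted p = 0.13) and Snord53 (1.47, adjusted p = 0.11) ended, and without the other-tissue arrays those of Cish (1.86, adjusted p = 0.074) at 21 days and Ciart (1.27, adjusted p = 0.27) at 3 months. Array weights gave 6468, 2495 and 3870, the covariates 990 and 1590 at 3 and 6 months, arrays of 1 age 1978 at 21 days, and the fit without other-tissue arrays 1594 at 6 months. With array medians subtracted the splits were 3084 above and 1360 below, 352 and 332, and 850 and 351, and with quantile normalization the last was 649 and 684.

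The difference of each mutant from C57Bl/6 was then compared with its difference at 21 days. Because array levels differ between ages, a difference in the range of the values between ages does not cancel here. In Largemyd at 3 months the difference exceeded that at 21 days most in Mmp3 (1.75±0.28), Igf2 (1.73±0.29), Cd28 (1.62±0.21), Aplnr (1.57±0.34) and AW551984 (1.34±0.23). It was lowest in Lcn2 (-4.09±1.18), Mir136 (-1.81±0.38), Agtr2 (-1.65±0.24), perinatal myosin (Myh8, -1.43±0.35) and Bdh1 (-1.43±0.27). At 6 months these were Pla2g2d (2.21±0.58), Cd28 (1.78±0.21), Sfrp1 (1.74±0.32), Snord53 (1.73±0.40) and Cmah (1.71±0.46) above. Those below were the atrophy ligase Fbxo32 (-2.59±0.60), Ostn (-2.23±0.37), Mettl11b (-2.21±0.39), Cyp4f39 (-2.19±0.30) and Myh8 (-2.09±0.35). In Dmdmdx they were Igf2 (1.59±0.29), Creb3l1 (0.98±0.21), Adamts9 (0.78±0.16) and Clic4 (0.45±0.09), against Arg1 (-1.69±0.37), Bdh1 (-1.53±0.27), Pla2g7 (-1.29±0.24), Hs3st5 (-1.27±0.25) and Slc4a4 (-1.21±0.25) at 3 months. At 6 months they were Igf2 (1.61±0.29), Serpinb6b (1.23±0.30), Pi15 (1.11±0.23), Peg3 (1.08±0.24) and Fbln7 (1.05±0.23) against Ostn (-3.06±0.37), Vsig4 (-2.01±0.45), Pla2g7 (-2.0±0.24), Arg1 (-1.80±0.37) and Fasn (-1.75±0.44). Limma called 526 (398 up) and 2129 (1218 up) genes for Largemyd at the 2 later ages, and 17 (5 up) and 100 (51 up) for Dmdmdx. The 3-month count for Largemyd was 343 without its 21-day replicate 1, and that for Dmdmdx 11 without C57Bl/6 replicate 2 at 3 months. The 6-month count for Dmdmdx was 171, 66, 61 and 58 without C57Bl/6 2 and Dmdmdx 3 at 21 days and Dmdmdx 2 and 3 at 6 months. Calls lost without 1 array were Lcn2 (without any of 14 arrays, adjusted p = 0.053 to 0.12) for Largemyd. For Dmdmdx at 3 months they were Arg1 (without any of 17 arrays, adjusted p = 0.052 to 0.12), Creb3l1 (without any of 12 arrays, adjusted p = 0.055 to 0.10), Clic4 (without C57Bl/6 at 3 months replicate 2, adjusted p = 0.053), Slc4a4 (without C57Bl/6 at 3 months replicate 5, adjusted p = 0.052) and Adamts9 (without Dmdmdx at 3 months replicate 1, adjusted p = 0.055). For Dmdmdx at 6 months they were Fasn (without any of 17 arrays, adjusted p = 0.051 to 0.10), Serpinb6b (without any of 10 arrays, adjusted p = 0.051 to 0.090) and Fbln7 (without C57Bl/6 at 21 days replicate 5 or Dmdmdx at 21 days replicate 3, adjusted p = 0.057 to 0.061). Without the high-Xist arrays 1 control is left at 6 months. The calls of Cmah, Fbxo32, Mettl11b, Ostn, Pla2g2d and Snord53 then ended for Largemyd and those of Arg1, Fasn, Fbln7, Serpinb6b and Vsig4 for Dmdmdx. With other-tissue arrays left out 2 genes passed for Dmdmdx at 3 months, none of the 9 named (adjusted p = 0.055 to 0.31), though Arg1, Creb3l1, Igf2 and Hs3st5 were -2.10, 1.05, 1.65 and -1.25 with fewer arrays. Myh8 (-1.08, adjusted p = 0.077) did not pass for Largemyd, nor Fasn (-1.79, adjusted p = 0.18) and Fbln7 (0.90, adjusted p = 0.055) for Dmdmdx at 6 months. Of the 9 only Igf2, Bdh1 and Adamts9 passed without the high-Xist arrays (adjusted p = 0.070 to 0.20 for the others). Array weights gave 200 and 1911 for Dmdmdx and 967 for Largemyd at 3 months, and the covariates 107, 262 and 932. Without dim genes Dmdmdx had 10 at 3 months. Dmdmdx split as 6 up and 8 down at 3 months and 103 and 38 at 6 months with array medians subtracted. Largemyd split as 308 and 163 at 3 months with quantile normalization.

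For the double mutant the difference from C57Bl/6 at 3 months exceeded that at 21 days most in Mmp12 (2.81±0.50), Aplnr (2.77±0.34), Fcrls (2.60±0.40), BC023105 (2.59±0.69) and Pmp2 (2.54±0.31). Its lowest values were in Ngp (-6.74±1.79), Lcn2 (-6.04±1.18), S100a8 (-5.0±1.43), Chil3 (-4.75±1.17) and Ibsp (-4.63±1.29). At 6 months the highest were Uty (3.46±1.16), C7 (3.45±0.97), tenomodulin (Tnmd, 2.79±0.48), BC023105 (2.52±0.69) and Fcrls (2.50±0.40), and the lowest Xist (-4.39±1.57), Lcn2 (-3.75±1.18), Chil3 (-3.63±1.17), Ostn (-2.84±0.37) and Fbxo32 (-2.78±0.60). Of the matrix genes 32 of 39 rose and 1 fell (34 and 1 over the list alone, camera p = 2.8e-27, or 0.045 with estimated correlation) at 3 months, such as Tnmd (2.47±0.48), Mfap4 (2.44±0.37) and Col15a1 (2.18±0.27). At 6 months 33 of 39 rose (35 over the list alone, camera p = 5.0e-28, or 0.020 with estimated correlation), such as Sfrp1 (2.23±0.32) and Mfap4 (2.13±0.37). Of the markers of fibro-adipogenic progenitors 12 of 21 rose (15 over the list alone, camera p = 2.3e-10, or 0.047 with estimated correlation) at 3 months. They followed at 6 months, where 16 of 21 rose (19 over the list alone, camera p = 8.1e-13, or 0.020 with estimated correlation). Limma called 3086 genes (1950 up) at 3 months and 3906 (2098 up) at 6 months, and 2592 at 6 months without dim genes. At 3 months array weights gave 5269 and the covariates 4920. With Xist and tissue markers as covariates the calls of BC023105 (1.65, adjusted p = 0.089), Chil3 (-0.85, adjusted p = 0.32) and Ibsp (0.06, adjusted p = 0.94) ended at 3 months. Those of BC023105 (1.51, adjusted p = 0.12), C7 (0.80, adjusted p = 0.21) and Chil3 (-1.02, adjusted p = 0.24) ended at 6 months, and against the 1 control without high Xist those of BC023105, C7, Uty and Xist. Uty is Y-linked, and as 4 of the 5 controls had high Xist, it was 0.24 and Xist -0.26 without such arrays. Calls lost without 1 array at 6 months were Xist (without any of 15 arrays, adjusted p = 0.050 to 0.074), Uty (without C57Bl/6 at 6 months 2 or 5, adjusted p = 0.054 to 0.059), Chil3 (without C57Bl/6 at 6 months replicate 3 or double mutant at 21 days replicate 5, adjusted p = 0.068 to 0.069) and Lcn2 (without C57Bl/6 at 6 months replicate 3, adjusted p = 0.058). Marrow markers were high in double mutant replicate 5 at 21 days and in 3 of the 5 controls at 3 months, and their part in Ngp, S100a8, Chil3 and Ibsp stays open.

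Part of the changes were shared by the lineages. Largemyd and Dmdmdx had 1235 genes up and 1499 down alike at 21 days, 1423 and 1322 at 3 months, and 1256 and 1019 at 6 months. Independent lists would share 230 and 353, 259 and 264, and 219 and 230. Genes that went opposite ways numbered 15, 2 and 30. The double mutant shared 1197 up and 1749 down, 1953 and 2297, and 1356 and 1132 with Dmdmdx, and 1359 and 2087, 1909 and 1487, and 2283 and 2425 with Largemyd. Correlations of log2 fold changes over all genes were 0.78, 0.75 and 0.73 for the single mutants, 0.67, 0.86 and 0.88 for the double mutant with Dmdmdx, and 0.83, 0.92 and 0.88 with Largemyd. Both comparisons of a pair use the same controls. Unchanged groups simulated with shared controls gave correlations of 0.46 to 0.53 and covariances of 0.008 to 0.013. Measured covariances were 0.088 to 0.142. With the controls split between the comparisons Largemyd and Dmdmdx shared 635 and 622, 880 and 658, and 725 and 480, and the correlations at 21 days were 0.64, 0.57 and 0.69. Gpnmb, Mmp12 and Myh3 were raised in all 3 mutants at 3 months. Pttg1 fell in both lineages with the Dmdmdx mutation at 6 months (-2.04±0.13 and -2.04±0.13) and was lower in the double mutant than in Largemyd (-1.51±0.13). Over all comparisons camera called 602 list results, 360 up and 242 down, and 64 of these held with an estimated correlation. These were 12 for proteases, 11 for complement, 9 each for macrophage markers and matrix genes, 6 each for chemokines and fibro-adipogenic markers, 3 each for imprinted growth genes and genes that vary between strains, 2 each for basement membrane and TGF-beta genes and 1 for clock genes. The plots of Gpnmb, Myh3, Postn and Pttg1 and of list medians show these groups.

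**Figure D4:**
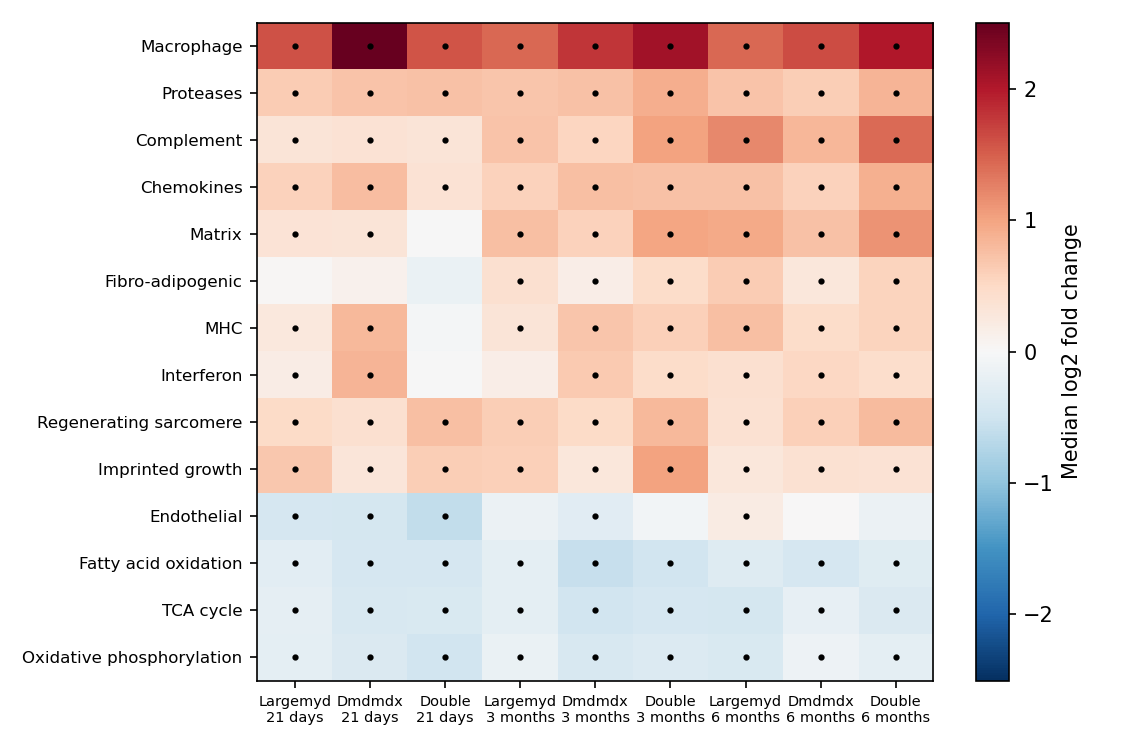
Median log2 fold change (colour) of 14 gene lists (vertical axis) in the 9 comparisons of a mutant with C57Bl/6 (horizontal axis). Each cell is the median over the measured genes of a list, and dots stand for lists called by camera.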

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

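The tests of sex were chosen only after the Xist values had been seen, and the others below, except 1 named there, before their results. Xist was high and the Y-linked genes were low in 11 of 60 arrays labelled male. The highest Y-linked mean of these arrays lay 3.21 log2 units below the lowest of the other 49, which speaks against tissue of both sexes mixed in 1 array and leaves animals of the other sex, or exchanged tubes, as explanations. Whether the 6-month differences of Largemyd from C57Bl/6 come from sex cannot be told apart from an effect of the lineage, since the slope of the log2 fold changes without these arrays was 0.72 with 1 control left, which has marrow markers. Of the called genes 95.1% kept their direction.

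Interferon-induced genes rose in Dmdmdx at 21 days with a median of 0.85, and lymph node RNA in some arrays is a candidate explanation. Without the arrays with other-tissue markers the median was 0.654 (mean difference 0.75 ± 0.22 against 0.98 ± 0.20, camera adjusted p = 1.55e-09), with 2 Dmdmdx and 4 C57Bl/6 arrays left. Lymph node RNA and an effect of the lineage cannot be told apart on so few arrays. A single array did not decide it, since the lowest median with 1 array left out was 0.745, without Dmdmdx replicate 1. A response of the muscle itself was not tested.

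Largemyd and the double mutant differed from both other lineages in the same direction at all 3 ages, 12 comparisons in all, in 7 genes, Bicc1, H2az2, Eno2, Lsm4, Jund, Ocel1 and B3gnt3 (4 higher and 3 lower). Of these Lsm4, Jund, Ocel1 and B3gnt3 lie on chromosome 8, where 0.3 were expected. Among genes in chromosomal order 1 neighbouring pair was in the set, and 27 of 10000 random sets had as many, so a chromosome segment of another strain carried along with the mutation may explain them. An effect of the Largemyd mutation on any of the 7 genes stays open as untested.

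Chance groupings of the arrays were tested with 100 splits of each comparison, counting the real one. Only the real split (1 of 100) reached its count in the mutants against C57Bl/6 at 21 days (4589, 5018 and 6759 genes against at most 3396, 4307 and 3815 for Largemyd, Dmdmdx and the double mutant), at 3 months for Largemyd (3773 against 2418) and the double mutant (5997 against 3099), and at 6 months (6483, 2763 and 5945 against 4834, 1155 and 3328). The same held for Largemyd against Dmdmdx (1782 against 961, 845 against 30 and 2843 against 890 by age), the double mutant against Dmdmdx (5475 against 2451, 402 against 79 and 913 against 41), and the double mutant against Largemyd at 3 and 6 months (227 against 6 and 268 against 214). For Dmdmdx against C57Bl/6 at 3 months 2 splits did (5606 against 7300, in the split that exchanged Dmdmdx replicate 1 for C57Bl/6 replicate 3). That is under 5% of the splits, yet a false grouping called more genes than the real one, so chance is not called excluded there. Nor was chance excluded for the double mutant against Largemyd at 21 days (9 splits, 1104 against 2910). For the non-additive effect and the differences from 21 days the residuals of a fit without the interaction were regrouped. This was chosen after splits of the arrays themselves, which keep the effects of lineage and reached 5 of the 9 counts in 5% or more, had been seen. Chance was excluded for the non-additive effect (3030, 635 and 1001 against 1390, 94 and 2 by age), for Largemyd (526 against 3430 in 1 other split, and 2129 against 143), for Dmdmdx (17 against 16 and 100 against 0) and for the double mutant (3086 against 198 and 3906 against 247). Splits that call several times the real count point to a structure of the samples, and what it is was not tested.

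Dixon's test singles out about 1 in 20 groups of 5 by chance, and it singled out 1 array in 32 of 132 groups of marker means and of Dmd, Utrn and Dag1 (24.2%). Lymph node means lay apart in C57Bl/6 replicate 2 at 21 days (10.19), 3 at 3 months (8.16) and 3 at 6 months (8.08), in Dmdmdx 5 at 3 months (10.42), and in the double mutant 5 at 3 months (6.66) and 4 at 6 months (8.84). Marrow means did in C57Bl/6 2 at 21 days (6.71) and 3 at 3 months (11.22) and in the double mutant 5 at 21 days (11.12) and 4 at 6 months (11.26). Bone means did in Dmdmdx 5 at 6 months (7.90) and in the double mutant 5 at 21 days (9.11) and 4 at 6 months (9.02), and cartilage in C57Bl/6 3 at 3 months (7.95). Skin means did in C57Bl/6 2 at 21 days (6.91) and 1 at 6 months (6.84), Largemyd 2 at 3 months (6.93), and Dmdmdx 5 at 21 days (7.01) and 5 at 3 months (6.36). Mammary means did in Largemyd 1 at 3 months (4.99) and 4 at 6 months (8.31) and Dmdmdx 5 at 3 months (6.29). Xist lay apart in C57Bl/6 5 at 3 months (10.60) and 3 at 6 months (5.54) and Dmdmdx 4 at 6 months (11.10), and the Y-linked mean in the same arrays (5.12, 8.70 and 5.06) and in Largemyd 3 at 21 days (8.79). Dmd lay apart in Dmdmdx 5 at 3 months (7.41), and Dag1 in Largemyd 4 at 21 days (10.80) and Dmdmdx 5 at 3 months (10.45). Among the other named genes 222 of 2220 groups had 1 array apart.

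Genes whose difference from C57Bl/6 differed from that at 21 days numbered 526 and 2129 for Largemyd at 3 and 6 months. They numbered 17 and 100 for Dmdmdx and 3086 and 3906 for the double mutant, yet with array weights Dmdmdx had 200 and 1911. Of the 13767 probe sets without a single gene symbol 4556 changed in at least 1 mutant against C57Bl/6, and they were left unnamed.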

How the results depend on the processing

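The arrays limit these results in several ways. Levels differ between ages, 11 arrays have the sex markers of females against their labels, 19 have raised markers of other tissue, for which immune cells within the muscle were not excluded, and 5 arrays per group leave the mutant comparisons open to single arrays. Genes changed with age were planned and not run, because RMA appears to have been run by age. No paired analysis was possible because each animal gave 1 array and replicate numbers only follow the order of the arrays. The alternatives without the arrays with high Xist, without those with other-tissue markers and with both kinds of marker as covariates were chosen after seeing the data, and the others before. Except where a setting leaves fewer arrays by construction, the cause of a move was not tested.

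Subtracting array medians, quantile normalization over all arrays, dropping genes below the 25th percentile, the mean of probe sets and a trended robust prior moved none of the 27 gene counts by more than 1.5 times. Dropping genes below the 50th percentile, which tests fewer genes, gave 3214 for the double mutant against Dmdmdx at 21 days and 10 and 2592 for the differences of Dmdmdx at 3 months and the double mutant at 6 months from those at 21 days. Array weights raised 16 counts: 8005 (Dmdmdx, 21 days), 6500 and 9236 (Largemyd and double mutant, 3 months) and 6214 (Dmdmdx, 6 months) against C57Bl/6, 1862, 1382 and 2700 between mutants at 3 months, 3019 and 746 for the double mutant against Dmdmdx and Largemyd at 6 months, 6468, 2495 and 3870 for the non-additive effect, and 967 (Largemyd, 3 months), 200 and 1911 (Dmdmdx) and 5269 (double mutant, 3 months) against 21 days.

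With the high-Xist arrays left out 12 counts fell and 2 were higher, with 1 C57Bl/6 array, which has marrow markers, left at 6 months: 3130 (Dmdmdx, 3 months), 924, 490 and 1799 (6 months) against C57Bl/6, 127, 150 and 359 between mutants at 3 months, 490 and 16 for Largemyd against Dmdmdx and the double mutant against Largemyd at 6 months, 299 and 58 for the non-additive effect, and 449, 269 and 1678 at 6 months against 21 days. Without the arrays with other-tissue markers 7 fell and 2 were higher: 3625 (Dmdmdx against C57Bl/6, 3 months), 374, 2060, 327, 254 and 790 between mutants at 21 days and 3 months, 161 at 6 months, 1594 (non-additive, 6 months) and 2 (Dmdmdx, 3 months against 21 days). With the covariates 2 fell and 10 were higher: 4552 (Dmdmdx against C57Bl/6, 6 months), 1754, 180, 528, 1526 and 70 between mutants, 990 and 1590 (non-additive), and 932, 107, 262 and 4920 against 21 days. With them 2 values turned direction, Ibsp in the double mutant at 3 months against 21 days (0.058) and the neutrophil list in Largemyd at 3 months (median 0.28), which shares genes with the marrow covariate. Xist, itself a covariate, was 0.00 there by construction.

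With the 20 arrays of 1 age, which leave fewer residual degrees of freedom, 4 counts fell, to 734 and 366 for Largemyd against Dmdmdx and the double mutant against Largemyd at 21 days, 1978 for the non-additive effect at 21 days and 471 for Largemyd against Dmdmdx at 3 months. With 2 groups alone they were 3184 for Dmdmdx against C57Bl/6 at 3 months, 723 and 45 between mutants at 21 days, 88, 143 and 1327 at 3 months and 8 at 6 months. Camera called 64 list results with an estimated correlation and fry 354, against 602, while the other settings gave 476 to 606. With the controls split, which leaves 2 or 3 controls to each comparison, genes changed alike numbered 1257, 1506 and 1832 at 21 days (Largemyd and Dmdmdx, double mutant and Dmdmdx, double mutant and Largemyd), 1538, 2639 and 1981 at 3 months, and 1205, 1307 and 3103 at 6 months. The correlations were 0.64, 0.57 and 0.69 at 21 days, 0.78 for the double mutant and Largemyd at 3 months, and 0.62, 0.77 and 0.80 at 6 months.

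With 1 array left out the counts ran from 819 to 2485, 3582 to 5466 and 548 to 1923 at 21 days for Largemyd against Dmdmdx, the double mutant against Dmdmdx and the double mutant against Largemyd. At 3 months they ran from 227 to 1394, 206 to 441 and 103 to 176, and at 6 months from 1677 to 2966, 590 to 957 and 71 to 346. The non-additive counts ran from 422 to 929 at 3 months and 627 to 1460 at 6 months, and those against 21 days from 343 to 698 for Largemyd at 3 months, and 11 to 24 and 58 to 171 for Dmdmdx. No other count moved by more than 1.5 times. Of 415 gene results named in the text, 52 changed their call in at least 1 of these fits, and so did 1 of 73 list results. Without the high-Xist arrays 90 gene results changed their call, without those with other-tissue markers 39, and in fits of 2 groups 31 of 318. The last, which keep the log2 fold changes, ended calls of Akr1e1, Alas2, C7, Chil3, Cyp4f18, Fbxo32, Ifi209, Irf7, Kera, Klra2, Krt19, Lgi1, Lrmda, Ly6a2, Mfap4, Mmp12, Ms4a4a, Oasl2, Pnpla3, Rsad2, Snord53, Thbs4, Tnc, Tnmd, Trim63, Ublcp1 and Ucp3, and fits of 1 age also of Depp1, Hamp, Inmt, Ppargc1a, Ppp1r3c and Rny1. Other scalings, priors or probe sets ended calls of Adamts9, Arg1, Cidec, Fasn, Ifi209, Lcn2, Mmp12 and Xist, and array weights 1 of Ciart.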

Other observations

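These hypotheses were written after the results were seen, and their tests were not run. Dmdmdx replicate 5 at 3 months had the lowest Dmd of its group (7.41), high Xist, lymph node and marrow markers, and Pttg1 near that of Largemyd. Another breeding or an exchanged tube may explain these, yet the part of lymph node and marrow RNA stays open. Without this array Largemyd against Dmdmdx at 3 months fell from 845 to 227 genes. Genotyping the RNA for the Dmdmdx mutation and strain variants would test breeding or exchange.

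H2-Ea was raised in Largemyd at every age (5.63±0.89, 5.94±0.89 and 4.65±0.89) and in the double mutant at 21 days (3.02±0.89) and 3 months (3.55±0.89). As C57Bl/6 carries a deleted H2-Ea promoter, a haplotype of another strain in the Largemyd colony is a likely source. Of the 7 genes that set Largemyd and the double mutant apart at all ages 4 lie on chromosome 8, with 1 neighbouring pair, and could come from a segment of such a strain. The change between Largemyd and Dmdmdx at 6 months was lost without the high-Xist arrays (2.99, adjusted p = 0.21). Genotyping the H2 region of all 4 lineages would test it.

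The double mutant at 21 days had raised Fkbp5 (1.73±0.34) against Dmdmdx, a glucocorticoid target, and more of the atrophy genes, a list whose call did not hold with an estimated correlation (adjusted p = 0.70). A stress hormone response in young double mutants might link these, and without double mutant replicate 1 the count against Dmdmdx was 3582 in place of 5475 and Fbxo32, Tnmd and Trim63 no longer passed. Blood corticosterone at 21 days would test it.

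Igf2 was raised in all 3 mutants at 3 months (2.21±0.21, 1.74±0.21 and 2.33±0.21), and in each its difference exceeded that at 21 days (1.73±0.29, 1.59±0.29 and 1.75±0.29). Since C57Bl/6 muscle loses Igf2 after birth, regenerating fibres that keep it could explain the growing gap, yet in Dmdmdx Igf2 missed the threshold without the arrays with other-tissue markers (1.65, adjusted p = 0.055). Staining for Igf2 and embryonic myosin in the same sections at the 3 ages would test it.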
